A study of Mus musculus with 14 samples.

How the data were processed

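Total RNA of mouse lung, extracted with Trizol per the labels, was measured on 14 Affymetrix mouse arrays, each hybridised with 6 µg of biotin-labelled cRNA. The deposited values are log2 probe set expression values, 1 per probe set and array, for 45101 probe sets. The submitters' processing notes name MAS5 and GCRMA without a version or a role for each, and the values span 0.446 to 16.1, a range that belongs to a log2 scale. Array medians lay between 4.60 and 4.75, no value was missing, and the values were used with no further scaling. Probe sets were named with the gene symbols of the platform annotation, and 34958 carried 1 symbol, 932 carried several and 9211 were left unnamed. The Entrez identifiers of 34754 probe sets matched the reference used for symbols, and 0 symbols changed. No genome coordinates were used here.

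Groups were taken from the labels alone: 4 arrays labelled Control, 4 labelled VALI, 3 labelled PBEF+/- and 3 labelled VILI PBEF+/-. The labels describe lungs of animals without stating that each array is a different animal, so p-values measure the spread between these samples. The number of arrays limits the precision. Replicate numbers in the titles did not pair the arrays across groups, and the arrays were treated as unpaired.

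A gene entered the tests when its probe set exceeded the array median in at least 3 of the 14 arrays, and the probe set with the highest mean stood for each gene. Of 18194 genes with a probe set, 11360 were tested. A linear model with the 4 groups was fitted to all arrays in limma 3.58.1 (R 4.3.3) with empirical Bayes moderation and a variance trend, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested. Adjusted p-values in the report come from limma, and a gene was called at an adjusted p under 0.05. The comparisons were VALI against Control, PBEF+/- against Control, VILI PBEF+/- against PBEF+/-, VILI PBEF+/- against VALI, and the interaction, which is the difference between both ventilation responses. Errors of fold changes are standard errors of the model, and errors of group means are standard deviations. Each ± after a log2 difference is such a standard error. Figures were drawn with matplotlib 3.10.9.

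Groups, comparisons, tests, the filter, the alternatives and 30 gene lists were chosen before the data were examined. The lists hold 408 entries, of which 332 were tested. They cover inflammatory cytokines and chemokines, NF-kB targets, IL-6 and STAT3 targets, immediate early genes, stretch and growth factor response, coagulation, heat shock proteins, oxidative stress and NRF2 targets, the unfolded protein response, NAD biosynthesis, the interferon response, the circadian clock, the glucocorticoid response, the cell cycle, extracellular matrix and endothelial barrier genes. They also hold markers of endothelial, alveolar type II, alveolar type I, club and ciliated cells, neutrophils, macrophages, B cells, T and NK cells, red blood cells, heart, skeletal muscle, fat and thymus, and sex-linked transcripts. Lists were tested with camera in limma at its preset inter-gene correlation of 0.01 and again with an estimated correlation, for the 28 lists with at least 3 measured members. The named genes are Nampt, then the 8 called genes with the largest rise and the 8 with the largest fall whose groups did not overlap, or the 5 with the smallest p where none was called, and up to 4 members of each list with the smallest p.

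Il6 in the arrays labelled VALI replicate 4 and PBEF+/- replicate 3 went against the other arrays of their groups. Their Nampt levels were the lowest in VALI and the highest in PBEF+/-. Every group has such an extreme array, and Nampt in VALI replicate 4 was not past Dixon's critical value for an outlier (ratio 0.517 against 0.829). Nampt alone does not single out these arrays. Given both genes, every comparison was run with all 14 arrays as labelled and again without these 2 arrays. The 2 arrays were picked from their own values after the data were examined, so counts and p-values without them are not independent evidence of a ventilation response. In that setting, 120 pairs of a gene and a comparison named in the report and called had more than 1 probe set. Another called probe set had the opposite sign in 0 of them, and in 50 a probe set did not pass.

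The model was tested on simulated data with the group sizes of the study, in which 200 of 11360 genes were changed. With all arrays, a log2 change of 1 was recovered for 76.1% of changed genes in VALI against Control and for 38.8% in the interaction, and a change of 2 for 95.5% and 82.1%. Between 6 and 12 unchanged genes were called in each comparison. The changed genes were drawn at random, with noise independent between genes. These shares therefore do not cover genes whose spread was widened by the 2 arrays, such as Il6. The absence of called genes as labelled cannot be judged by them.

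The alternatives chosen in advance were no filter, a filter above the median in at least 12 of 14 arrays, quantile normalization, median centring, all probe sets, a fit with only the groups compared, no variance trend, array weights, the replicate number as a block, a minimum of 2-fold, and each array left out in turn. A pseudocount was planned for linear values only and was not applied to log2 values. The fit without the 2 arrays, the sex pattern as a covariate, and the arrays with the female pattern alone were added after the data were seen. Il6 in most unventilated arrays was within the low mode of the values. A fold change against a group whose mean lay below the array median is limited by the array background and is given as a lower bound.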

Results

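The data are expression values of whole mouse lung on 14 arrays. The series set out to compare lungs given pre-B-cell colony-enhancing factor (PBEF), lungs injured by mechanical ventilation, and lungs given both. The arrays were labelled Control (n = 4, given PBS), VALI (n = 4, ventilated for 4 hours), PBEF+/- (n = 3, not ventilated) and VILI PBEF+/- (n = 3, ventilated for 4 hours). The sample labels name a tidal volume of 40 ml/kg, while the series text names 30 ml/kg and recombinant human PBEF given into the trachea. Animals were 18-22 weeks old except in VILI PBEF+/-, where they were 8-12 weeks old. The group names are used here as labelled, since the labels leave open whether PBEF+/- stands for a genotype or for the protein given. PBEF is the product of Nampt, the rate-limiting enzyme of NAD salvage, which is also secreted.

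Nampt itself, on the probe set with its highest mean, was not called in any of the 5 comparisons as labelled. Its mean log2 level was 10.18 ± 0.17 (SD, n = 4) in Control, 9.94 ± 0.53 (SD, n = 4) in VALI, 9.75 ± 0.83 (SD, n = 3) in PBEF+/- and 10.23 ± 0.83 (SD, n = 3) in VILI PBEF+/-. PBEF+/- differed from Control by -0.43 (adjusted p = 0.74), and VALI differed from Control by -0.25 (adjusted p = 0.76). Within PBEF+/-, replicates 1 and 2 read 9.34 and 9.21 and replicate 3 read 10.71. Within VILI PBEF+/-, replicates 1 and 2 read 10.79 and 10.62, while replicate 3 read 9.28, between PBEF+/- replicates 1 and 2. When PBEF+/- replicate 3 and VALI replicate 4 were left out, the log2 difference was -0.91 between PBEF+/- and Control and 0.96 between VILI PBEF+/- and PBEF+/-. No p is given for these, since the 2 arrays were left out for their Nampt and Il6 values. The other probe sets for Nampt also had their lowest means in PBEF+/-, 9.16 ± 1.02 (SD, n = 3) and 5.95 ± 1.37 (SD, n = 3).

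Il6, the cytokine interleukin-6, separated ventilated from unventilated lungs in 12 of the 14 arrays. The 4 Control arrays read 2.09 to 2.45 on the log2 scale and VALI replicates 1 to 3 read 9.60 to 9.85, while VALI replicate 4 read 2.78. PBEF+/- replicates 1 and 2 read 2.10 and 2.56, while replicate 3, labelled as not ventilated, read 10.87. The 3 VILI PBEF+/- arrays read 12.75, 12.33 and 10.32. These 2 arrays stood with the arrays of the other condition on other lists too. The mean log2 score of the oxidative stress and NRF2 targets, taken as the deviation from the mean of all arrays, was -0.73 in VALI replicate 4 against 0.90 to 1.14 in VALI replicates 1 to 3, and 1.06 in PBEF+/- replicate 3 against -1.08 and -1.19 in replicates 1 and 2. The comparisons below are therefore given with all arrays as labelled and without these 2 arrays. They were picked from their own values, so the p-values of genes and lists without them are conditional on that choice.

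**Figure D1:**
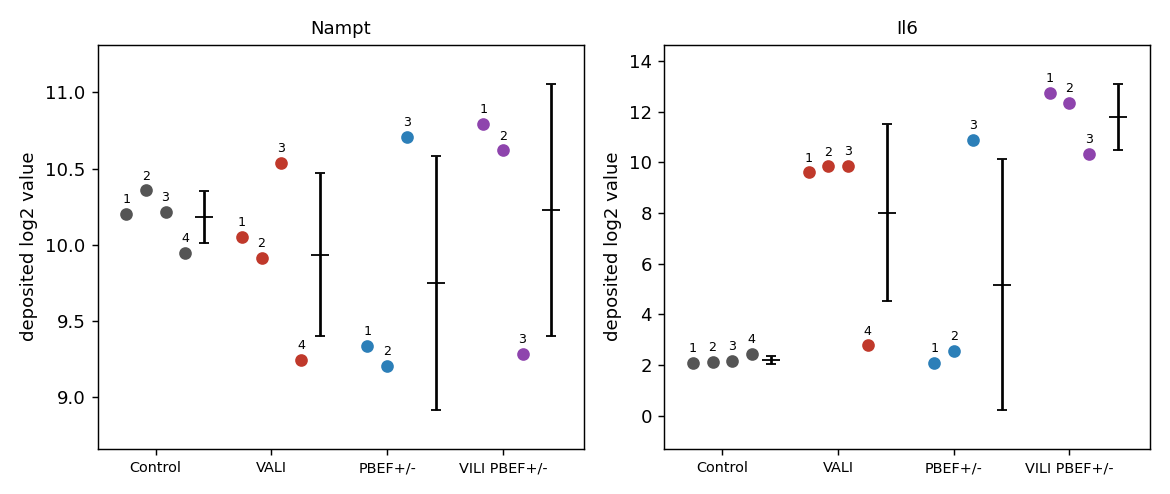
Deposited log2 values of Nampt and Il6 in each array, by group, with replicate numbers beside the points and bars for the group mean and SD. Il6 in VALI replicate 4 (2.78) lies near the Control arrays, and Il6 in PBEF+/- replicate 3 (10.87) lies among the ventilated arrays.

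The comparison of VALI with Control asks what ventilation changed in lungs not labelled PBEF+/-. As labelled, mean Il6 was 2.21 ± 0.16 (SD, n = 4) in Control and 8.02 ± 3.49 (SD, n = 4) in VALI, a spread set by VALI replicate 4. The genes with the smallest p, none of them called, were Grina (log2 difference 0.70 ± 0.10, adjusted p = 0.0734), Selplg, the ligand of P-selectin on leukocytes (0.59 ± 0.09), Ivns1abp (0.55 ± 0.09), Itgb8, an integrin that activates TGF-beta (1.25 ± 0.21), and the noncoding Snhg1 (1.22 ± 0.20, adjusted p = 0.0765). limma called 0 of 11360 genes, with 2075 at an unadjusted p under 0.05. Leaving out VALI replicate 4 gave 680 called genes and leaving out PBEF+/- replicate 3 gave 288. The count was 7 without PBEF+/- replicate 1, 3 without Control replicate 1 or VALI replicate 2, 2 without Control replicate 4, and 1 without Control replicate 3 or VALI replicate 1.

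Members of several lists were past the threshold when adjusted over the list alone, with 0 in each over all genes. Of the oxidative stress and NRF2 targets, 10 of 13 rose when adjusted over the list alone, among them Slc7a11, the cystine importer (3.99 ± 1.16), and Hmox1, which degrades heme (3.22 ± 1.05). On the same basis 7 of 13 neutrophil markers, 6 of 14 IL-6 and STAT3 targets, 6 of 20 immediate early genes, 5 of 13 cytokines and chemokines, 5 of 13 macrophage markers, 4 of 14 NF-kB targets, 4 of 11 coagulation genes and 2 of 13 stretch genes rose, and so did 1 member each of the unfolded protein, T and NK cell and skeletal muscle lists. On this basis 4 of 12 club and ciliated cell markers, 4 of 11 alveolar type I markers and 2 of 15 endothelial markers fell, and so did 1 member each of the IL-6 and STAT3, immediate early, coagulation and endothelial barrier lists. Camera called 14 of 28 lists at the preset correlation and 0 when the correlation was estimated, where the smallest was adjusted p = 0.302 with an estimated correlation. Other splits of the same arrays gave up to 17 lists, so the preset calls do not set these groups apart.

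VALI lungs without the 2 arrays (n = 3) differed from Control (n = 4) in members of the cytokine, neutrophil and oxidative stress lists. With an estimated correlation the first 2 lists did not pass (adjusted p = 0.198 and 0.0791 with an estimated correlation). Il6 was at least 188-fold higher (log2 7.56 ± 0.44), and its p is not given, since VALI replicate 4 was left out for its Il6 value. Mmp8, the collagenase of neutrophils, rose at least 113-fold (6.82 ± 0.36), and Il1r2, the decoy receptor for interleukin-1, at least 78.6-fold (6.30 ± 0.35). Slc7a11 rose at least 39.0-fold (5.29 ± 0.28, adjusted p = 2.98e-06), and the tight junction gene Cldn4 (6.44 ± 0.40), the AP-1 subunit Fosl1 (6.43 ± 0.41) and Doc2b, a calcium sensor of exocytosis (5.89 ± 0.32), rose as well. Acta1, the actin of skeletal muscle, rose by 6.49 ± 1.25, with VALI replicate 1 at 15.16 and replicates 2 and 3 at 9.40 and 8.85. The largest falls were in Cckar, a cholecystokinin receptor (-3.75 ± 0.23), Dcdc2a (-3.63 ± 0.25), the kinesin Kif26b (-2.94 ± 0.40), Mycl (-2.88 ± 0.45), the somatostatin receptor Sstr4 (-2.74 ± 0.49), Akap14 (-2.70 ± 0.44), the retinoic acid receptor Rarb (-2.66 ± 0.32) and Ccdc151, a gene of motile cilia (-2.59 ± 0.38).

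In this setting limma called 1933 of 11360 genes, 742 higher and 1191 lower, and 547 of them changed at least 2-fold. The groups did not overlap in any array for 1904 of the called genes, where chance gives 5.71% of genes and 35.5% of all genes tested did so. The count was 985 without VALI replicate 1 and 1039 without VALI replicate 2. All 3 VALI arrays left here had the female pattern, against 2 of 4 Control arrays, so ventilation is partly confounded with sex.

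Of the 30 lists, the neutrophil markers had the most members that rose, 11 of 13 without the 2 arrays, also 11 adjusted over the list alone. They included Clec4e, a receptor for microbial glycolipids (5.06 ± 0.44), and Cxcr2, the chemokine receptor of neutrophils (2.64 ± 0.26), and the list had adjusted p = 0.0791 with an estimated correlation. Of the cytokines and chemokines, 8 of 13 rose (10 adjusted over the list alone), including the neutrophil chemokines Cxcl2 (at least 30.9-fold, 4.95 ± 0.49) and Cxcl1 (9.11-fold, 3.19 ± 0.48) and Il1b (3.34 ± 0.57). The cytokine list had adjusted p = 0.198 with an estimated correlation. Of the IL-6 and STAT3 targets, 8 of 14 rose (10 adjusted over the list alone), with the feedback inhibitor Socs3 at 2.74 ± 0.18, Timp1 at 3.03 ± 0.49 and the acute phase gene Saa3 at 3.73 ± 0.81. The haptoglobin gene Hp on that list fell (-0.54 ± 0.12), and the list had adjusted p = 0.269 with an estimated correlation. Of the NF-kB targets 4 of 14 rose (8 adjusted over the list alone), namely Bcl3 (2.56 ± 0.19), the cyclooxygenase Ptgs2 (3.38 ± 0.36), P-selectin Selp (2.51 ± 0.43) and Nfkbiz (1.35 ± 0.28). The NF-kB list had adjusted p = 0.255 with an estimated correlation.

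Oxidative stress and NRF2 targets rose in 10 of 13 members, also 10 adjusted over the list alone, with adjusted p = 0.00693 with an estimated correlation. As labelled it had adjusted p = 0.302 with an estimated correlation, and the arrays left out were low or high on this list, so the smaller p is not evidence that the list held. Its members included Srxn1, which repairs peroxiredoxins (12.1-fold, 3.60 ± 0.21), Hmox1 (18.9-fold, 4.24 ± 0.26) and the thioredoxin reductase Txnrd1 (3.82-fold, 1.93 ± 0.12). Immediate early genes rose in 9 of 20 members (11 adjusted over the list alone), with Myc at 2.96 ± 0.34, Egr1 at 1.81 ± 0.22 and Junb at 1.96 ± 0.26, while Klf4 fell. That list had adjusted p = 0.159 with an estimated correlation. Of the stretch and growth factor genes 4 of 13 rose (8 adjusted over the list alone), among them the EGF receptor ligand Ereg (at least 20.4-fold, 4.35 ± 0.25) and the urokinase receptor Plaur (1.89 ± 0.15), while Vegfa and Pdgfb fell (the Vegfa call ended in 16 of 23 alternatives). The stretch list had adjusted p = 0.255 with an estimated correlation. Of the coagulation genes 5 of 11 rose, also 5 adjusted over the list alone, including tissue factor F3 (2.32 ± 0.19), the protein C receptor Procr (1.15 ± 0.21) and Plat (1.29 ± 0.28), and thrombomodulin Thbd fell. The coagulation list had adjusted p = 0.198 with an estimated correlation. Of the unfolded protein response 4 of 14 rose (4 adjusted over the list alone), Asns (1.14 ± 0.16), Atf4 (1.24 ± 0.23), Trib3 (1.70 ± 0.37) and Chac1 (1.75 ± 0.54, a call that ended in 15 of 23 alternatives). The unfolded protein list had adjusted p = 0.601 with an estimated correlation. Of the glucocorticoid response 4 of 12 rose (4 adjusted over the list alone), among them Fkbp5 (2.51 ± 0.71) and Sgk1 (0.65 ± 0.17). Control arrays differed in Fkbp5, at 11.98 and 12.04 in replicates 2 and 3 and 9.97 and 8.72 in replicates 1 and 4. Their glucocorticoid scores were 0.31 and 0.27, and -0.72 and -1.20, in that order, against 0.28 to 0.60 in VALI replicates 1 to 3. The glucocorticoid list had adjusted p = 0.361 with an estimated correlation.

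Markers of resident lung cells were lower in part. Of the club and ciliated cell markers 8 of 12 fell (10 adjusted over the list alone), with the ciliary dynein gene Dynlrb2 at -0.81 ± 0.11 and the club cell enzyme Cyp2f2 at -0.59 ± 0.08, while the keratin Krt8 rose (1.66 ± 0.22). The club and ciliated list had adjusted p = 0.361 with an estimated correlation. Of the alveolar type I markers 5 of 11 fell (5 adjusted over the list alone), among them Rtkn2 (-1.16 ± 0.26) and Ager (-0.34 ± 0.09). The type I list had adjusted p = 0.664 with an estimated correlation. Of the endothelial markers 5 of 15 fell (7 adjusted over the list alone), with the transcription factor Sox18 at -1.11 ± 0.15 and the VEGF receptor Kdr at -0.94 ± 0.22, and Lyve1 rose. The endothelial marker list had adjusted p = 0.361 with an estimated correlation. Of the endothelial barrier genes 3 of 14 fell (4 adjusted over the list alone), the receptor Tek (-0.89 ± 0.10) and its ligands Angpt1 (-0.79 ± 0.21) and Angpt2 (-0.77 ± 0.19). Of the 9 B cell markers 5 fell (8 adjusted over the list alone), with the complement receptor Cr2 at -1.39 ± 0.29 and Cd79b at -0.97 ± 0.25. The B cell list had adjusted p = 0.361 with an estimated correlation. Of the alveolar type II markers 0 of 12 were called by limma over all genes or adjusted over the list alone, with the surfactant gene Sftpc at -0.15 ± 0.05.

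The remaining lists held few called members in VALI against Control without the 2 arrays. Of the macrophage markers 2 of 13 rose, the endotoxin co-receptor Cd14 (1.57 ± 0.25) and the mannose receptor Mrc1 (0.89 ± 0.24). The macrophage list had adjusted p = 0.361 with an estimated correlation. In the NAD list Bst1, which consumes NAD, rose (0.98 ± 0.28) and the mitochondrial deacetylase Sirt3 fell (-0.57 ± 0.14). In the interferon list Ifit2 (-0.75 ± 0.16) and Gbp2 (-0.70 ± 0.19) fell, in the clock list Nr1d1 fell (-1.03 ± 0.25) and Bhlhe40 rose (0.95 ± 0.27), in the matrix list Postn fell (-0.41 ± 0.12, a call that ended in 16 of 23 alternatives), and in the T and NK cell list Il7r rose (0.97 ± 0.18). Adjusted over the list alone, these lists held 2, 2, 2, 2, 0 and 1 such members in that order. Of 6 skeletal muscle markers Acta1 alone rose, adjusted over the list alone as well. The muscle list had adjusted p = 0.601 with an estimated correlation. limma called 0 members among 13 heat shock proteins, 7 cell cycle genes, 12 heart markers, 3 fat markers, 4 sex-linked transcripts, 2 thymus markers and 1 red blood cell marker, over all genes or adjusted over the list alone, and the last 2 lists were too small for camera.

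**Figure D2:**
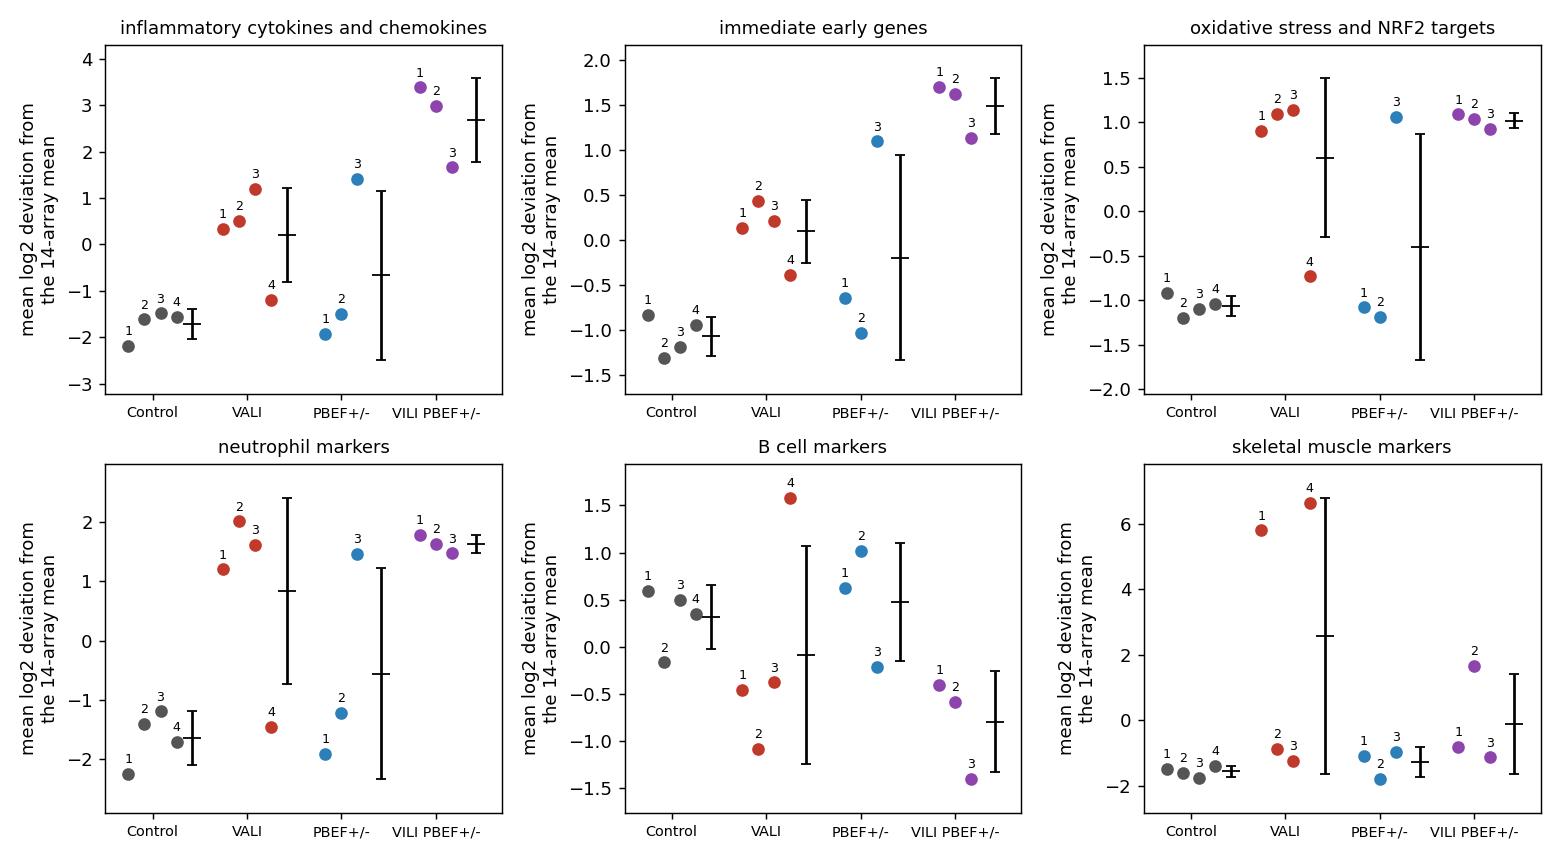
Mean log2 deviation of the members of 6 gene lists from their mean over all 14 arrays, by array and group, with bars for the group mean and SD. The neutrophil score of VALI replicate 4 is -1.46 against 1.20 to 2.01 in VALI replicates 1 to 3, and that of PBEF+/- replicate 3 is 1.45 against -1.91 and -1.22 in replicates 1 and 2.

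PBEF+/- against Control asks how unventilated lungs labelled PBEF+/- differed from Control, and no gene was called. The genes with the smallest p as labelled (n = 3 and 4) were Zfp319 (log2 difference -0.68 ± 0.12), the replication factor Cdc6 (1.31 ± 0.25), the early growth response gene Egr1 (1.76 ± 0.36), Ccn1, a matrix protein of the growth factor response (1.20 ± 0.26), and Selplg (0.41 ± 0.10), each with adjusted p = 0.593. With the 2 arrays left out (n = 2 and 4) they were Snhg1 (0.53 ± 0.09), Plekhm2 (-0.81 ± 0.15), the placental growth factor Pgf (-1.11 ± 0.22), Egr1 (1.19 ± 0.25) and Adgrg1 (-0.68 ± 0.14), each with adjusted p = 0.45. The immediate early score was 1.09 in PBEF+/- replicate 3, -0.65 and -1.03 in replicates 1 and 2, and -1.31 to -0.83 in Control. Egr1 and the nuclear receptor Nr4a1 (1.58 ± 0.44) led the immediate early genes as labelled. Of these 20 genes, 3 were higher when adjusted over the list alone, and 0 over all genes. On the same basis 1 of 13 stretch genes (Ccn1) was higher, and 1 of 14 IL-6 and STAT3 targets (Hp, -0.52 ± 0.14) was lower. In the other setting, 3 of 12 heart markers were higher when adjusted over the list alone, among them Pln (0.85 ± 0.24), and 4 of 13 heat shock proteins were lower, among them Hspb1 (-1.0 ± 0.28).

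limma called 0 of 11360 genes in PBEF+/- against Control as labelled, with 938 at an unadjusted p under 0.05, and 0 without the 2 arrays, with 1257 at an unadjusted p under 0.05. Camera called 12 lists at the preset correlation as labelled and 0 when it was estimated, where the smallest was adjusted p = 0.427 with an estimated correlation. The PBEF+/- group then holds 2 arrays, 1 of each sex pattern. Leaving out Control replicate 1 as well gave 1 called gene, and leaving out VILI PBEF+/- replicate 3 gave 2. Without PBEF+/- replicate 1 or 2 that group holds 1 array, so gene counts of such fits are not given.

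VILI PBEF+/- against PBEF+/- asks how ventilated and unventilated lungs differed in the groups labelled PBEF+/-. Their animals also differed in age (8-12 and 18-22 weeks), so this comparison cannot separate ventilation from age. As labelled (n = 3 and 3), the genes with the smallest p, none called, were Rgs16, a regulator of G protein signalling (log2 difference 2.48 ± 0.39), Rab3a (-0.62 ± 0.10), the chromatin remodeller Chd1 (0.70 ± 0.12), the monocyte chemokine Ccl2 (5.27 ± 0.90) and the macrophage growth factor Csf1 (0.86 ± 0.15), each with adjusted p = 0.11. Members of several lists were higher when adjusted over the list alone, with 0 in each over all genes: 13 of 13 cytokines and chemokines, 12 of 13 heat shock proteins, 16 of 20 immediate early genes, 11 of 14 NF-kB targets, 9 of 14 IL-6 and STAT3 targets, 9 of 13 stretch genes and 5 of 13 neutrophil markers. On this basis 4 of 12 club and ciliated cell markers, 2 of 9 B cell markers, 1 NF-kB target and 1 stretch gene were lower. The smallest list p was adjusted p = 0.214 with an estimated correlation. limma called 0 of 11360 genes, with 2355 at an unadjusted p under 0.05. Without PBEF+/- replicate 3 the count was 2157, and without VILI PBEF+/- replicate 3 it was 12.

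When the 2 arrays were left out (n = 3 and 2), Il6, Fosl1, Mmp8 and Il1r2 had some of the largest positive differences, as in VALI against Control. Il6 was at least 709-fold higher (log2 9.47 ± 0.53), and its p is not given, since PBEF+/- replicate 3 was left out for its Il6 value. Fosl1 (7.39 ± 0.49), Mmp8 (6.67 ± 0.43) and Il1r2 (6.23 ± 0.42) rose. The hyaluronan synthase Has1 (7.43 ± 0.46), Cxcl2 (at least 143-fold, 7.16 ± 0.59), the aggrecan-cleaving protease Adamts4 (6.70 ± 0.68) and Ccl2 (at least 85.2-fold, 6.41 ± 0.67) were also among the 8 largest rises. The largest falls were in Cckar (-4.73 ± 0.28), Dcdc2a (-4.12 ± 0.30), the ubiquitin ligase Rnf186 (-3.51 ± 0.68), Kif26b (-3.48 ± 0.48), the growth factor Wnt2 (-3.36 ± 0.50), Hs6st2, a heparan sulfate sulfotransferase (-3.13 ± 0.28), Shisa2 (-3.02 ± 0.72) and Wdr19, a gene of transport in cilia (-2.84 ± 0.26). limma called 3003 of 11360 genes, 1267 higher and 1736 lower, 1100 of them at least 2-fold. Groups did not overlap for 2989 of them, where chance gives 20% of genes and 51.0% of all genes tested did so. The count was 1820 without VILI PBEF+/- replicate 1 and 1908 without VILI PBEF+/- replicate 2.

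All 13 measured cytokines and chemokines rose in VILI PBEF+/- against PBEF+/- without the 2 arrays, also adjusted over the list alone, including Cxcl1 (39.8-fold, 5.32 ± 0.58). This cytokine list had adjusted p = 0.13 with an estimated correlation. NRF2 targets rose in 10 of 13 members (10 adjusted over the list alone), with Hmox1 at 29.8-fold (4.90 ± 0.31), Srxn1 at 3.99 ± 0.25 and Slc7a11 at 4.73 ± 0.33, and adjusted p = 0.0325 with an estimated correlation, against 0.407 as labelled, where the same reservation applies. Heat shock proteins rose in 12 of 13 members (12 adjusted over the list alone), among them the inducible chaperone Hspa1b (13.1-fold, 3.71 ± 0.71) and Hspb1 (1.67 ± 0.30), and Cryab fell. The heat shock score was 1.49 in VILI PBEF+/- replicate 3 against 0.39 and 0.31 in replicates 1 and 2, and it was 0.52 in Control replicate 1. The heat shock list had adjusted p = 0.306 with an estimated correlation. Immediate early genes rose in 16 of 20 (16 adjusted over the list alone), with Myc at 5.39 ± 0.41 and Junb at 3.66 ± 0.31, and Klf4 fell. The immediate early list had adjusted p = 0.111 with an estimated correlation. NF-kB targets rose in 11 of 14 (12 adjusted over the list alone), with Bcl3 at 3.90 ± 0.23, and Traf1 fell. Here the NF-kB list had adjusted p = 0.195 with an estimated correlation. Neutrophil markers rose in 10 of 13 (11 adjusted over the list alone), with Cxcr2 at 3.11 ± 0.31 and adjusted p = 0.13 with an estimated correlation. B cell markers fell in 8 of 9 (8 adjusted over the list alone), with the IgM receptor Fcmr at -2.40 ± 0.45 and Cd79b at -1.84 ± 0.30, and adjusted p = 0.279 with an estimated correlation. Club and ciliated cell markers fell in 7 of 12 (8 adjusted over the list alone), with Dynlrb2 at -1.24 ± 0.13, and Krt8 rose (2.25 ± 0.27). Here the airway list had adjusted p = 0.587 with an estimated correlation.

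The differences between ventilated and unventilated lungs in the groups labelled PBEF+/- and in the other groups ran in the same direction across genes. In the former they include the difference in age. The log2 fold changes of the 2 comparisons correlated across 11360 genes with Pearson's r = 0.675 and Spearman's rho = 0.586 as labelled, and with r = 0.786 and rho = 0.702 without the 2 arrays. Genes are not independent replicates, and the comparisons share no array. As labelled, r was reached by 6 of 100 splits of the same arrays, so chance cannot be excluded for it. Without the 2 arrays, 1315 genes were called in both comparisons, 1311 of them with the same sign. Of these, 533 rose in both, against 82.8 by independence, and 778 fell in both, against 182. As labelled, 0 genes were called in both. The 2 arrays were left out for their values, and sex is then partly confounded with ventilation in both comparisons. The excess over independence is therefore no test of a shared ventilation response.

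**Figure D3:**
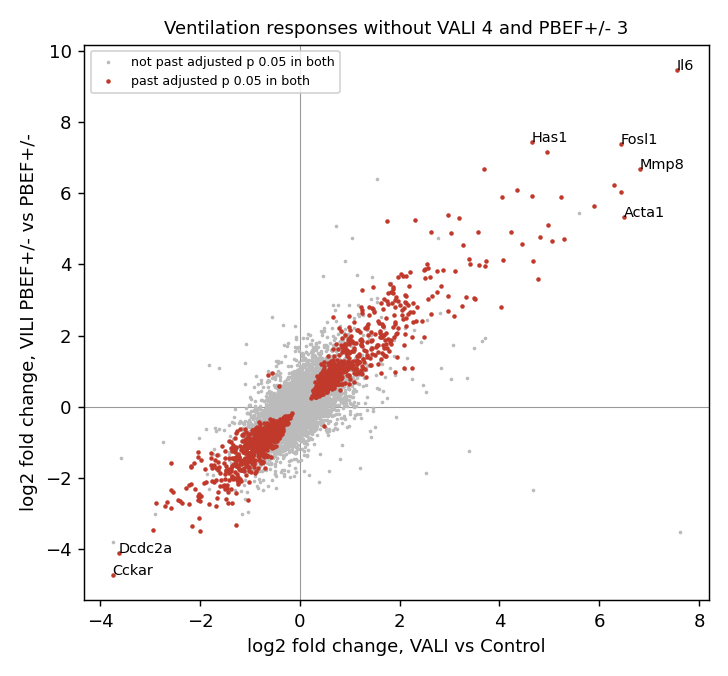
Log2 fold changes of 11360 genes in VALI against Control (horizontal) and in VILI PBEF+/- against PBEF+/- (vertical), without VALI replicate 4 and PBEF+/- replicate 3, with genes called in both comparisons in red. Il6 was higher by at least 7.56 and at least 9.47, and Cckar fell by 3.75 and 4.73.

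VILI PBEF+/- against VALI asks how ventilated lungs labelled PBEF+/- differed from the other ventilated lungs, whose animals also differed in age. Of the genes tested without the 2 arrays (n = 3 and 3), 13 were higher in VILI PBEF+/- and 0 were lower. The monocyte chemokines Ccl2 (27.2-fold, log2 4.77 ± 0.60, adjusted p = 0.0396) and Ccl7 (at least 9.50-fold, 3.25 ± 0.51, adjusted p = 0.0497), the AP-1 subunit Fosb (20.4-fold, 4.35 ± 0.57), Rgs16 (2.28 ± 0.33) and Ereg (1.71 ± 0.27) led them. The others were thrombospondin Thbs1 (1.51 ± 0.24), Ccn1 (1.45 ± 0.21), the small GTPase Gem (1.34 ± 0.21), the ERK phosphatase Dusp5 (1.22), Fos (1.21), Phlda1 (1.08), Csf1 (0.98) and the stress response gene Gadd45a (0.97), the last 5 named after their values were seen. Each of these 13 calls ended in 11 to 20 of its 22 or 23 alternatives, most often for Thbs1 (20 of 23). As labelled (n = 3 and 4) the genes with the smallest p, none called, were Rgs16 (2.49 ± 0.37), Csf1 (0.89 ± 0.14), Ccl2 (5.13 ± 0.84), the histone H1f2 (-0.50 ± 0.08) and Zfp46 (0.78 ± 0.13), each with adjusted p = 0.109.

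Many cytokine and immediate early genes stood higher in VILI PBEF+/- than in VALI. Adjusted over the list alone as labelled, 8 of 13 cytokines and chemokines, 9 of 14 NF-kB targets, 10 of 20 immediate early genes, 4 of 13 stretch genes and 6 of 13 heat shock proteins were higher, with 0 over all genes, and the smallest list p was adjusted p = 0.104 with an estimated correlation. In the fit without the 2 arrays, 2 cytokines, 3 immediate early genes and 3 stretch genes were called over all genes, and 9, 15 and 6 adjusted over the list alone. These lists passed in that fit, with adjusted p = 0.0467, 0.0145 and 0.0392 with an estimated correlation in that order, and each had 0.104 as labelled. Of the NF-kB targets 0 were called over all genes and 10 adjusted over the list alone, such as Nfkbiz (1.21 ± 0.30). Among ventilated lungs the NF-kB list had adjusted p = 0.0628 with an estimated correlation. Neutrophil markers did not pass in any of 13 members, with a median log2 difference of 0.04.

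limma called 0 of 11360 genes in VILI PBEF+/- against VALI as labelled, with 1191 at an unadjusted p under 0.05, and 13 without the 2 arrays, with 858 at an unadjusted p under 0.05. Groups did not overlap for these 13 genes, where chance gives 10% of genes and 17.9% of all genes tested did so. As labelled, 9 genes were called without PBEF+/- replicate 3 or without VILI PBEF+/- replicate 3, and 1 without VALI replicate 3. The 13 calls were 107 without VILI PBEF+/- replicate 3, 5 without Control replicate 2, 2 without VALI replicate 3, and 0 without any of Control replicates 1, 3 and 4, VALI replicates 1 and 2, and VILI PBEF+/- replicates 1 and 2.

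The interaction asks whether ventilated and unventilated lungs differed by another amount in the groups labelled PBEF+/- than in the others, and no gene was called. It carries the age difference in full, since VILI PBEF+/- alone was 8-12 weeks old. As labelled, the genes with the smallest p were Lix1l (0.97 ± 0.17), Pik3ip1, an inhibitor of PI3 kinase (-1.0 ± 0.19), Cbr3 (-1.22 ± 0.23), Chd1 (0.82 ± 0.16, adjusted p = 0.508) and Zfp319 (0.86 ± 0.17, adjusted p = 0.554). In the fit without the 2 arrays they were Phlda1 (1.84 ± 0.23, adjusted p = 0.0725), the proton-sensing receptor Gpr4 (1.51 ± 0.24), the endothelial transcription factor Sox7 (1.15 ± 0.20), Ccl2 (4.87 ± 0.87) and Thbs1 (1.91 ± 0.35, adjusted p = 0.289). Adjusted over the list alone, 10 of 13 heat shock proteins, such as Hspa8 (0.69 ± 0.19), and 3 of 13 cytokines, such as Csf2 (2.54 ± 0.76), had larger differences in the PBEF+/- groups as labelled, with 0 over all genes. With the 2 arrays left out, 12 heat shock proteins, 10 immediate early genes and 8 cytokines did so, with 0 over all genes, and the smallest list p in either setting was adjusted p = 0.381 with an estimated correlation. limma called 0 of 11360 genes as labelled, with 634 at an unadjusted p under 0.05, and 0 without the 2 arrays, with 1176 at an unadjusted p under 0.05. Leaving out VILI PBEF+/- replicate 3 in addition gave 41 called genes. Gene counts without PBEF+/- replicate 1 or 2 are not given, since 1 array is then left in that group.

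Sex and muscle transcripts differed between arrays of a group. Xist, the transcript of the inactive X, and the Y-linked Eif2s3y gave the sex pattern. It was male in 2 of 4 Control arrays, 1 of 4 VALI arrays and 1 of 3 PBEF+/- arrays. Of the VILI PBEF+/- arrays, 0 of 3 had the male pattern. Without the 2 arrays, every ventilated array had the female pattern, while Control replicates 1 and 4 and PBEF+/- replicate 2 had the male pattern. Sex is then partly confounded with ventilation in both comparisons of ventilated with unventilated lungs. The muscle creatine kinase Ckm read 12.59 in VALI replicate 1 and 13.70 in VALI replicate 4, against 7.08 and 6.66 in VALI replicates 2 and 3 and 7.30 to 7.94 in Control.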

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

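The tests of explanations in this part, the choice of the 2 doubted arrays included, were chosen only after the results were seen, while the interaction tests of the gene lists were planned. Of 64 checks of a group of 4 arrays for a value far from the others, 9 passed Dixon's critical value, 4 in Control and 5 in VALI, where chance gives about 1 in 20.

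In the VALI group, replicate 4 stood apart from the other 3 arrays on 5 measures: Il6 (log2 2.78), the NRF2 target score (-0.73), the cell cycle score (0.80), the T and NK cell marker score (0.60) and the sex-linked transcript score (1.25). Il6 in Control replicate 4 (2.45) stood apart from the other Control arrays, all at low values. Control replicate 1 stood low on the coagulation score (-0.58) and on the alveolar type II marker score (-0.33). Control replicate 3 stood high on the red blood cell markers (2.02), where 1 gene was measured.

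The array labelled VALI replicate 4 lacked most of the Il6 and NRF2 target response of the other VALI arrays. PBEF+/- replicate 3, labelled as not ventilated, carried that response. An exchange of labels between these arrays may account for both. Correlations were taken over 11308 genes, without Nampt and the cytokine, NF-kB, IL-6 and STAT3, sex and muscle lists. Neutrophil, immediate early and NRF2 genes stayed in, so the correlations are not independent of the Il6 values by which the arrays were picked. VALI replicate 4 correlated at 0.359 with PBEF+/- replicates 1 and 2 and at -0.324 with VALI replicates 1 to 3, a gap of 0.684. PBEF+/- replicate 3 correlated at 0.487 with VALI replicates 1 to 3 and at -0.570 with PBEF+/- replicates 1 and 2. Which arrays, if any, were exchanged stays open. PBEF+/- replicate 3 correlated at 0.585 with VILI PBEF+/-, and VALI replicate 4 correlated at 0.251 with Control. The muscle score of VALI replicate 4, 6.64, went with the VALI label. That score was 5.79 in VALI replicate 1, -0.87 and -1.22 in VALI replicates 2 and 3 and -1.79 to -0.95 in PBEF+/-. A weak ventilation response of VALI replicate 4 stays open too. Its Cxcl1 read 7.18, against 4.89 to 5.83 in Control and 5.97 and 5.65 in PBEF+/- replicates 1 and 2. Its immediate early score was -0.39, against -1.31 to -0.83 in Control and -0.65 and -1.03 in PBEF+/- replicates 1 and 2. Other tissue, such as muscle, diluting the lung RNA of VALI replicate 4 is argued against, since its alveolar type II markers differed from VALI replicates 1 to 3 by a median of -0.28 (SD 0.23 over 12 genes) while Il6 differed by -6.99. Sex is argued against for PBEF+/- replicate 3, whose Il6 lay 8.78 above that of PBEF+/- replicate 1 with the same female pattern, and for VALI replicate 4 sex and ventilation response cannot be told apart, since 0 other ventilated arrays had the male pattern.

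Camera's planned test of the interaction called 13 lists at the preset correlation, and none of these calls held with an estimated correlation. The interaction carries the age difference in full, since VILI PBEF+/- alone was 8-12 weeks old. With a positive value for a larger difference between ventilated and unventilated lungs in the PBEF+/- groups, the median log2 difference was 1.19 for cytokines and chemokines, 0.46 for NF-kB targets, 0.51 for immediate early genes, 0.48 for stretch genes, 1.17 for heat shock proteins, 0.35 for the unfolded protein response, 0.30 for endothelial markers and 0.19 for alveolar type I markers. It was -0.56 for the cell cycle, -0.46 for macrophage markers, -0.83 for B cell markers, -0.46 for T and NK cell markers and -3.53 for skeletal muscle markers, which were high in VALI replicates 1 and 4. The count of 13 lists was reached by 32 of 100 splits of the arrays, up to 16, and chance cannot be excluded. These splits shuffled all 4 group labels, so the difference between ventilated and unventilated lungs can enter their counts. They therefore cannot decide the question.

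Cytokine and immediate early genes were higher in VILI PBEF+/- than in VALI replicates 1 to 3. VILI PBEF+/- replicates 1 and 2 lay above all of VALI replicates 1 to 3 on 31 of 33 measured members each. Replicate 3 did so on 28, so the pattern was not limited to replicates 1 and 2, but it was smaller in replicate 3. Its cytokine score was 1.66, against 3.38 and 2.98 in replicates 1 and 2 and 0.33 to 1.19 in VALI replicates 1 to 3. Its immediate early score was 1.13, against 1.70 and 1.62, and 0.13 to 0.44, in that order. PBEF+/- replicate 3 had 1.42 and 1.09 on these 2 scores. Chance gives 25% of members, but genes of a list can move together and these lists were picked after their values were seen. The share is therefore no test against chance. The age of the animals cannot be told apart from the group, since 0 VALI arrays had the age given for VILI PBEF+/-. PBEF, as the design names it, remains an open biological explanation, and so does age. PBEF+/- replicate 3 lay above VALI replicates 1 to 3 on 26 of the members, so its place among the groups bears on this comparison.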

How the results depend on the processing

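The fits without the 2 arrays, the sex covariate and the fits with female-pattern arrays alone were chosen only after the results were seen, and the other alternatives were planned. The correlation of the ventilation responses kept its sign in every alternative run. For gene counts of 0 as labelled, with the unadjusted counts given in the report, VALI against Control gave 27 with only the groups compared, 4689 with array weights, 1933 without the 2 arrays and 41 with female-pattern arrays alone. PBEF+/- against Control gave 5 with female-pattern arrays alone. The comparison of VILI PBEF+/- with PBEF+/- gave 2 over all probe sets, 3363 with array weights and 3003 without the 2 arrays. The comparison of VILI PBEF+/- with VALI gave 1 with only the groups compared, 1711 with array weights and 13 without the 2 arrays. The interaction gave 20 with array weights and 1 with female-pattern arrays alone. Leaving out each array in turn gave 0 to 680, 0 to 0, 0 to 2157, 0 to 9 and 0 to 0 genes in the order of the report. The highest counts came without VALI replicate 4 (680) and without PBEF+/- replicate 3 (2157).

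Nampt moved past the threshold with array weights in VILI PBEF+/- against PBEF+/- (1.15) and against VALI (0.68 as labelled, 0.68 without the 2 arrays). Leaving out each array, its log2 differences ran from -0.45 to -0.01 for VALI against Control, -0.91 to -0.16 for PBEF+/- against Control, 0.20 to 0.96 for VILI PBEF+/- against PBEF+/-, 0.01 to 0.77 against VALI and 0.45 to 1.20 for the interaction, and r ran from 0.567 to 0.756. With the 2 arrays left out, the same ranges were -0.20 to 0.11, -0.99 to -0.85, 0.68 to 1.43, -0.22 to 0.54 and 0.69 to 1.45, and r ran from 0.669 (without PBEF+/- replicate 1) to 0.808. The highest values in VILI PBEF+/- against PBEF+/- (1.43) and in the interaction (1.45) came without VILI PBEF+/- replicate 3. Since the 2 arrays were left out for their Nampt and Il6 values, tests of Nampt without them show nothing further, and their p-values are not given. Its difference of -0.01 between VALI and Control was 0.0243 after quantile normalization and 0.0591 after median centring.

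Without the 2 arrays, the 1933 genes of VALI against Control were 5037 with array weights and 547 at 2-fold, and 985 to 2524 with each array left out. The 0 of PBEF+/- against Control were 1 with no filter, 1 over all probe sets, 1 with only the groups compared and 41 with female-pattern arrays alone, and 0 to 1892 with each array left out, where the highest came without PBEF+/- replicate 1. The 3003 of VILI PBEF+/- against PBEF+/- were 4555 over all probe sets, 1226 with only the groups compared, 1554 with array weights and 1100 at 2-fold, and 1820 to 3710 with each array left out. The 13 of VILI PBEF+/- against VALI were 0 with no filter, 6 with the stricter filter, 8 after quantile normalization, 2 with only the groups compared, 7 with no variance trend, 1851 with array weights, 0 with the replicate block and 36 with female-pattern arrays alone, and 0 to 107 with each array left out. The 0 of the interaction were 1 with median centring, 1 with array weights and 10 with female-pattern arrays alone, and 0 to 1242 with each array left out.

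The lists called at the preset correlation, 14, 12, 14, 11 and 13 as labelled, were 0, 0, 0, 0 and 0 with an estimated correlation. PBEF+/- against Control gave 6 lists without the 2 arrays, VILI PBEF+/- against VALI gave 7 with the replicate block, and the interaction gave 5 with female-pattern arrays alone. With each array left out they ran 12 to 16, 6 to 14, 12 to 16, 8 to 16 and 6 to 14, where PBEF+/- against Control had 6 without PBEF+/- replicate 3 and the interaction had 6 without VILI PBEF+/- replicate 3. The lists called without the 2 arrays, 16, 6, 14, 10 and 14, were 1, 0, 1, 3 and 0 with an estimated correlation. PBEF+/- against Control then gave 12 with no filter. With each array left out they ran 12 to 17, 6 to 8, up to 16, 8 to 14 and 7 to 17. The lowest count for VILI PBEF+/- against PBEF+/- is not given, since it came from a fit with 1 PBEF+/- array. The interaction had 7 without VILI PBEF+/- replicate 3.

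A group left with 1 array was assumed to vary like the others. Among genes named for a comparison, apart from Nampt, whose small differences turned as given above, 0 of 826 alternatives as labelled and 0 of 3366 without the 2 arrays turned the direction. Of the former 74 passed the threshold where the gene had not, and of the latter 27 did so and 383 ended a call. These genes were named for a small p or a large difference in the same arrays. A turn of direction was therefore unlikely from the start, and its absence is no independent support. The replicate block is listed for completeness, since of 19 pairs of arrays with like numbers 7 had a residual correlation above 0.1 and 6 were best matched by their own number. Apart from the counts at 2-fold, which follow from the added minimum, and the estimated correlation, which widens the null, the cause was not tested. Genes near the array background in unventilated lungs, such as Il6, have fold changes limited by that background.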

Other observations

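The tests of the clock genes and of other splits, and leaving out the 2 arrays, were chosen only after the results were seen, while the gene lists and their tests were planned. Members of further lists changed in VILI PBEF+/- against PBEF+/- without the 2 arrays. Of 14 members of the unfolded protein response 7 rose (7 adjusted over the list alone), including Chac1, which degrades glutathione (7.87-fold, log2 2.98 ± 0.64), and the ER chaperone Hspa5 (1.60-fold, 0.68 ± 0.20), with adjusted p = 0.378 with an estimated correlation. The unfolded protein score was 0.87 in VILI PBEF+/- replicate 3 against 0.22 and 0.15 in replicates 1 and 2. Of 11 coagulation genes 5 rose (5 adjusted over the list alone), with tissue factor F3 at 2.4 ± 0.23 and Plaur at 2.57 ± 0.18, and adjusted p = 0.224 with an estimated correlation. In the matrix list Lox, the collagen cross-linking enzyme (2.49 ± 0.43), and Col4a1 (0.65 ± 0.17) rose, and in the cell cycle list Rrm2 (-0.86 ± 0.25) and Mcm5 (-0.73 ± 0.20) fell. In the macrophage list the scavenger receptor Msr1 (1.19 ± 0.26) and Cd14 (1.74 ± 0.30) rose, and the monocyte receptors Ccr2 (-1.54 ± 0.34) and Csf1r (-0.48 ± 0.12) fell. The deacetylase Sirt1 (0.58 ± 0.15) and the methyltransferase Nnmt (1.61 ± 0.27) rose in the NAD list, and Sirt3 fell (-0.94 ± 0.16).

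Clock genes differed among the 6 arrays labelled as unventilated other than PBEF+/- replicate 3, whose label is in doubt. Dbp, an output gene of the circadian clock, read 10.31 and 10.39 in Control replicates 2 and 3, against 12.15 and 12.81 in Control replicates 1 and 4 and 12.34 and 12.80 in PBEF+/- replicates 1 and 2. The clock gene Arntl ran 6.63 and 6.53 in Control replicates 2 and 3 and 3.43 to 4.08 in the other 4 of these arrays, and the glucocorticoid target Fkbp5 read 11.98 and 12.04 in Control replicates 2 and 3. PBEF+/- replicate 3, left out here, had the female pattern and read 10.14 for Dbp, 4.35 for Arntl and 13.18 for Fkbp5. Sex stays open: PBEF+/- replicate 1, with the female pattern, lay 1.95 above the higher of the 2 female-pattern Control arrays in Dbp, but it is 1 array, and the male-pattern arrays were all high. Tissue collected at different times of day could give such a split, and it stays open, since the labels give no time and the mean of Arntl and Clock ran opposite to Dbp in 11 of 15 pairs of the 6 arrays.

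Other splits of the same arrays into groups of the same sizes gave the following counts. A count of 0 genes is reached by every split, so for such counts the splits test nothing. As labelled this held for VALI against Control (35 of 35 splits, up to 1 gene), PBEF+/- against Control (35 of 35, up to 1), VILI PBEF+/- against VALI (35 of 35, up to 6) and the interaction (100 of 100, up to 2429). The last number points to a structure of the samples, and what it is was not tested. VALI against Control had 14 lists, reached by 11 splits, up to 17, PBEF+/- against Control had 12, reached by 12, up to 15, and VILI PBEF+/- against VALI had 11, reached by 25, up to 18. The correlation of the ventilation responses, 0.675, was reached by 6 of 100 splits, up to 0.791. Chance cannot be excluded for these list counts and the correlation.

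For VILI PBEF+/- against PBEF+/- as labelled the 10 splits are too few for a share under 0.05: the real split had 0 genes, reached by 10, against up to 98 in the others, and 14 lists, reached by 1, against up to 13. Without the 2 arrays, the 1933 genes of VALI against Control were reached by 1 of 35 splits, the real one, with up to 51 in the others, and the correlation of 0.786 by 1 of 100 splits, the real one, with up to 0.763 in the others. Since 2 arrays had been left out for their values, these splits do not exclude chance. The 16 lists of VALI against Control were reached by 5 splits, up to 17, so chance cannot be excluded for them. PBEF+/- against Control and the interaction were not split in this setting. The comparisons of VILI PBEF+/- with PBEF+/- and with VALI had 10 splits each, too few for a share under 0.05. The comparison of VILI PBEF+/- with PBEF+/- had 3003 genes, reached by 1, with up to 719 in the others, and 14 lists, reached by 3, with up to 16. The comparison with VALI had 13 genes, reached by 1, with up to 6 in the others, and 10 lists, reached by 8, with up to 14.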
